A study of Ceratopteris richardii with 6 samples.

How the data were processed

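RNA was sequenced from whole sporophyte seedlings of Ceratopteris richardii, a homosporous fern, of the wild type RNWT1. The sporophyte is the generation of the fern that bears roots and fronds. The labels give 3 groups of 2 libraries each: a mock group, and seedlings kept on medium with 2 µM 2,4-D, a synthetic auxin, for 24 h or 48 h. The seedlings came from spores cultured for 30 days, at which point the treated ones were moved to new medium, per the labels' protocols. Whole seedlings were frozen, RNA was extracted with TRIzol, and libraries were made with Illumina protocols, also per the labels' protocols. The deposited table names the mock columns as 0 days, and the samples used here hold 0 untreated libraries at 24 h and 0 at 48 h. When the mock seedlings were harvested is not stated beyond the 30 days of culture. If it was at 0 days, as the column names read, time on new medium and plant age differ between mock and treated seedlings together with 2,4-D. Nothing in the labels says whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The 1d and 2d columns were matched to libraries by treatment time and replicate number, and the 0d columns to the mock libraries, the only group with no treatment time. The number of columns left without a library was 0.

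The values are TPM per assembled gene, which give its share of the transcripts of a library on a fixed scale after correction for gene length, deposited by the authors in 1 table of the whole series and rounded there to hundredths. The file's name credits them to RSEM. Per the submitters' processing notes, Trim Galore 0.5.0, Bowtie2 2.3.4.3, STAR 2.7.2b and RSEM 1.3.2 were used and the build TAIR10 was named, with no role or order for any of them. The gene IDs are those of Trinity, a tool that assembles transcripts from reads without a genome. They carry 5 prefixes (LA, LE, RO, RT and SHA), whose meaning is not given in the sources used here. Each column summed to the same total, apart from rounding, over the 88641 genes listed. TPM keep no read depth, so the depth of each library is unknown, and no counting interval or detection floor can be given. TPM are also shares of 1 total, so a rise of abundant genes lowers the values of all others.

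The table does not pair its IDs with gene names. Of the 88641 IDs, 0 matched the locus tags, protein accessions or symbols of the 36816 genes in the RefSeq table of the Ceratopteris richardii assembly C.richardii_v2. For this reason 0 of the 25 gene lists fixed in advance (auxin response, auxin transport, cell cycle, cell wall, photosynthesis, stress, markers of spores and reproductive tissue, and others) could be tested, and no gene coordinates or functions are given. Genes are described by ID, by ID prefix, by abundance and by time course instead. The rule for naming genes allows at most 2 IDs in each direction per comparison where no names exist. They were those with the largest fitted change among genes past the threshold, with a mean of at least 1 TPM and no overlap between the 4 libraries compared. The parts of an ID up to its last g number mark a component of the assembly, and genes of 1 component can share reads. Of the genes tested, 7.68% shared a component with another tested gene.

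Of the genes listed, 17371 were at 0 in all 6 libraries. Genes with at least 1 TPM in at least 2 libraries were kept (32225 genes), which held between 98.97% and 99.25% of each library's TPM. Values were transformed as log2(TPM + 1), and fold changes are on that scale, which understates changes of low genes. All 6 libraries were fitted in 1 model with the group as a factor, using limma 3.58.1 in R 4.3.3 with a mean-variance trend. The fit had 3 residual degrees of freedom per gene and a prior of 4.18. Tests were two-sided, and p-values were adjusted by the Benjamini-Hochberg method within each of 3 comparisons, with a threshold of 0.05. A moderated F test over both comparisons with mock gave the genes changed at either time. Values are means ± SD over the 2 libraries of a group, and errors of log2 fold changes are standard errors from the model. The overlap of calls in the same direction at both times was planned, while its subdivision, the other time-course classes, the tests on ID prefixes and the split by abundance were chosen after the data were seen. Enrichment of ID prefixes among called genes was tested with Fisher's exact test, two-sided, against all other tested genes and adjusted over 30 tests; genes are not independent replicates. Both comparisons with mock share the mock libraries, so 100 simulations of unchanged groups were run with the fitted variances. Fits with a separate mock library for each treatment time were added after the data were seen.

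The procedure was tested on simulated data for all 32225 genes, with 200 changed genes in each comparison. For 24 h against mock it recovered 10% of genes changed by 0.5 on the log2 scale, 43.5% of those changed by 1 and 88.5% of those changed by 2, with 7 false calls among 98. In the simulated 48 h comparison with mock the shares were 13.8%, 50.7% and 91.0%, with 7 false calls among 114. For 48 h against 24 h they were 12.3%, 49.2% and 93.4%, with 6 false calls among 114. Far more than 200 genes were called in the data, where the Benjamini-Hochberg cut-off on p is then more lenient. The simulated shares therefore do not give the recovery in the data. The main tests, the gene lists, the naming rule and the alternatives were fixed before the data were examined, except where said otherwise. The alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 TPM, rescaling of the TPM by trimmed means (30% of log ratios and 5% of mean levels trimmed at each end), quantile normalization, the replicate number as a block, leaving out each library, no mean-variance trend, only the 4 libraries compared, and other thresholds.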

Results

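The transcriptome of whole Ceratopteris richardii sporophyte seedlings was measured in a mock group and after exposure to the synthetic auxin 2,4-D, with 2 libraries each for mock, 24 h and 48 h. The series is titled for genes regulated by auxin in the sporophyte, the plant generation with roots and fronds. The deposited table gave TPM for 88641 assembled genes, of which 32225 reached 1 TPM in at least 2 libraries and were tested. Read depth per library is unknown. Between 56149 and 59991 genes were above 0 in a library, and between 29057 and 31295 reached 1 TPM. The 100 most abundant genes held 19.2% and 19.6% of all TPM in the mock libraries, 16.1% and 16.7% at 24 h, and 20.2% and 20.8% at 48 h.

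Libraries of a group lay closer to each other than to any library of another group. Across genes, log2(TPM + 1) of the 2 libraries correlated with r = 0.985 in mock, 0.987 at 24 h and 0.989 at 48 h. The correlation between mock and 24 h libraries ranged from 0.962 to 0.968, and that between mock and 48 h libraries from 0.928 to 0.931. The median absolute difference between replicates was 0.14 in mock, 0.12 at 24 h and 0.12 at 48 h on the log2 scale. In no pair of libraries did more than 0.767% of tested genes have identical TPM. The 48 h libraries parted from the other 4 on the first principal component, which held 60.2% of the variance, and the mock and 24 h libraries parted on the second, which held 24.1%.

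**Figure D1:**
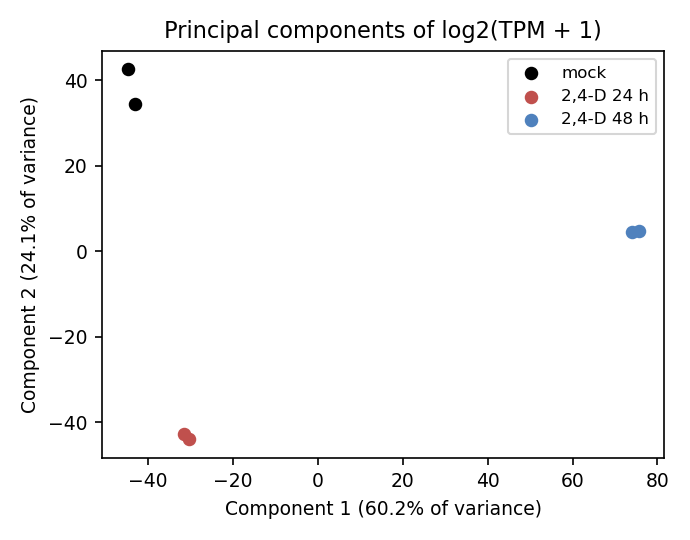
Principal components of log2(TPM + 1) over the 32225 tested genes, with the share of variance on each axis in percent. Each point is a library, coloured by group. The 48 h libraries sit at 74.1 and 75.6 on component 1, while the other 4 lie between -44.7 and -30.3.

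The first comparison asked which genes differed after 24 h of 2,4-D. In the deposited TPM, 5164 of the 32225 genes (16.0%) changed against mock, 3531 of them higher and 1633 lower, by limma with Benjamini-Hochberg adjustment. Among the changed genes, 666 were at least 2-fold higher and 453 at least 2-fold lower, and 32 were at least 8-fold higher and 25 at least 8-fold lower. The assembled gene RO_TRINITY_DN25257_c0_g3 rose from 1.54 ± 0.75 TPM in mock to 233 ± 23.9 TPM (SD, n = 2 libraries), a log2 fold change of 6.55 ± 0.21 (SE) with a limma adjusted p of 1.14e-05. RO_TRINITY_DN3901_c0_g1 rose from 4.01 ± 0.35 to 260 ± 12 TPM, a ratio of means of 64.9. The largest fall was that of SHA_TRINITY_DN8813_c0_g1, from 225 ± 61.0 TPM to 0.925 ± 0.163 TPM, with a log2 fold change of -6.85 ± 0.19 and a limma adjusted p of 8.19e-06. RO_TRINITY_DN3683_c0_g1 fell from 258 ± 35.3 to 1.55 ± 0.56 TPM. With a pseudocount of 5 the order turned, with log2 fold changes of -5.32 for RO_TRINITY_DN3683_c0_g1 and -5.25 for SHA_TRINITY_DN8813_c0_g1. Both falling genes were higher in mock replicate 2 than in mock replicate 1 (268 against 181 TPM for SHA_TRINITY_DN8813_c0_g1, and 282 against 233 TPM for RO_TRINITY_DN3683_c0_g1). RO_TRINITY_DN25257_c0_g3 is 1 of 3 genes of its assembly component, so reads could be divided among them. The summed TPM of that component went from 9.42 in mock to 237 at 24 h.

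The balance of directions at 24 h depended on the scaling. The median log2 fold change of all tested genes was 0.098, and trimmed-mean rescaling moved it to -0.0041. After that rescaling 4674 genes changed, 2150 higher and 2524 lower, so the share of higher genes went from 68.4% to 46.0%. Quantile normalization gave 2400 higher and 2257 lower genes, a share of 51.5%. Both alternatives centre the log ratios between libraries near 0, so they shift the balance by construction. The count was 3093 with no filter on low genes. It also fell when any library was left out, most without either 24 h library or mock replicate 2, and less without the others. Each such fit leaves a lone library in a group and fewer residual degrees of freedom, which alone can lower a count.

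After 48 h of 2,4-D the difference from mock was wider. Of the 32225 genes, 12365 (38.4%) changed, 5109 of them higher and 7256 lower, by limma with Benjamini-Hochberg adjustment. At least 2-fold changes were found in 1681 higher and 1759 lower genes, and changes of at least 8-fold in 109 higher and 60 lower genes. LE_TRINITY_DN51550_c0_g1 showed the largest rise, from 1.38 ± 0.37 TPM in mock to 262 ± 0.86 TPM (SD, n = 2 libraries), with a log2 fold change of 6.79 ± 0.13 (SE) and a limma adjusted p of 2.8e-07. RO_TRINITY_DN25257_c0_g3, the gene with the largest rise at 24 h, was the next, at 221 ± 45.8 TPM. SHA_TRINITY_DN22019_c0_g2 fell from 339 ± 3.0 TPM to 2.87 ± 0.18 TPM, a log2 fold change of -6.46 ± 0.06 with a limma adjusted p of 1.97e-08. LE_TRINITY_DN428_c0_g1 fell from 188 ± 5.0 to 2.2 ± 0.21 TPM. Apart from RO_TRINITY_DN25257_c0_g3, these genes were not called at 24 h: there LE_TRINITY_DN51550_c0_g1 was at 1.39 ± 0.18 TPM, SHA_TRINITY_DN22019_c0_g2 at 332 ± 4.7 TPM and LE_TRINITY_DN428_c0_g1 at 218 ± 6.1 TPM. No untreated seedlings at 48 h were analysed here. The median log2 fold change of all genes was -0.083. After trimmed-mean rescaling 12023 genes changed, 6297 higher and 5726 lower, so the share of higher genes went from 41.3% to 52.4%; quantile normalization gave 5722 higher and 6254 lower, a share of 47.8%. Without 48 h replicate 2, the number of lower genes was 4792.

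**Figure D2:**
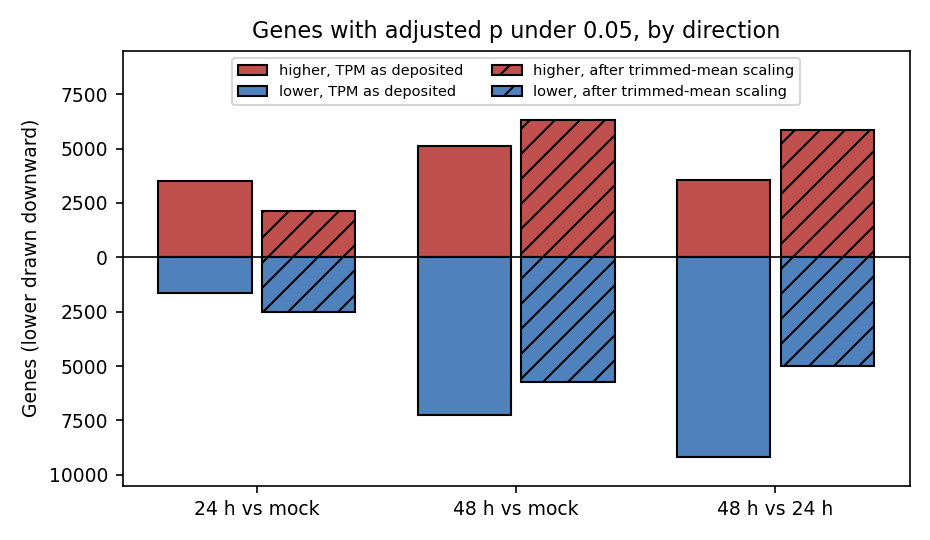
Number of genes with an adjusted p under 0.05 (vertical axis; higher genes upward, lower genes downward) in each of 3 comparisons, from the TPM as deposited (plain bars) and after trimmed-mean rescaling (hatched bars). At 24 h against mock, 3531 higher and 1633 lower genes became 2150 and 2524.

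The direct comparison of the treatment times asked which genes differed between 48 h and 24 h. It gave 12756 changed genes (39.6%), 3569 higher and 9187 lower at 48 h, by limma with Benjamini-Hochberg adjustment. The median log2 difference of all genes, 48 h minus 24 h, was -0.18. After rescaling that median was -0.0011 and 10849 genes changed, 5837 higher and 5012 lower, so the share of higher genes went from 28.0% to 53.8%. Quantile normalization gave 4928 higher and 5802 lower genes, a share of 45.9%. Leaving out 48 h replicate 2 gave 8224 genes, 5719 of them lower, and leaving out 24 h replicate 1 gave 8471, 5672 of them lower. The IDs named by the rule were again LE_TRINITY_DN51550_c0_g1 (log2 difference of 6.78 ± 0.13, SE), SHA_TRINITY_DN22019_c0_g2 (-6.43 ± 0.06) and LE_TRINITY_DN428_c0_g1 (-6.10 ± 0.07). The fourth, RT_TRINITY_DN9150_c0_g2, fell from 11.7 ± 2.6 TPM in mock to 3.97 ± 1.37 TPM at 24 h and rose to 161 ± 9.8 TPM at 48 h (SD, n = 2 libraries). Its log2 difference between the times was 5.05 ± 0.20, with a limma adjusted p of 3.95e-06.

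**Figure D3:**
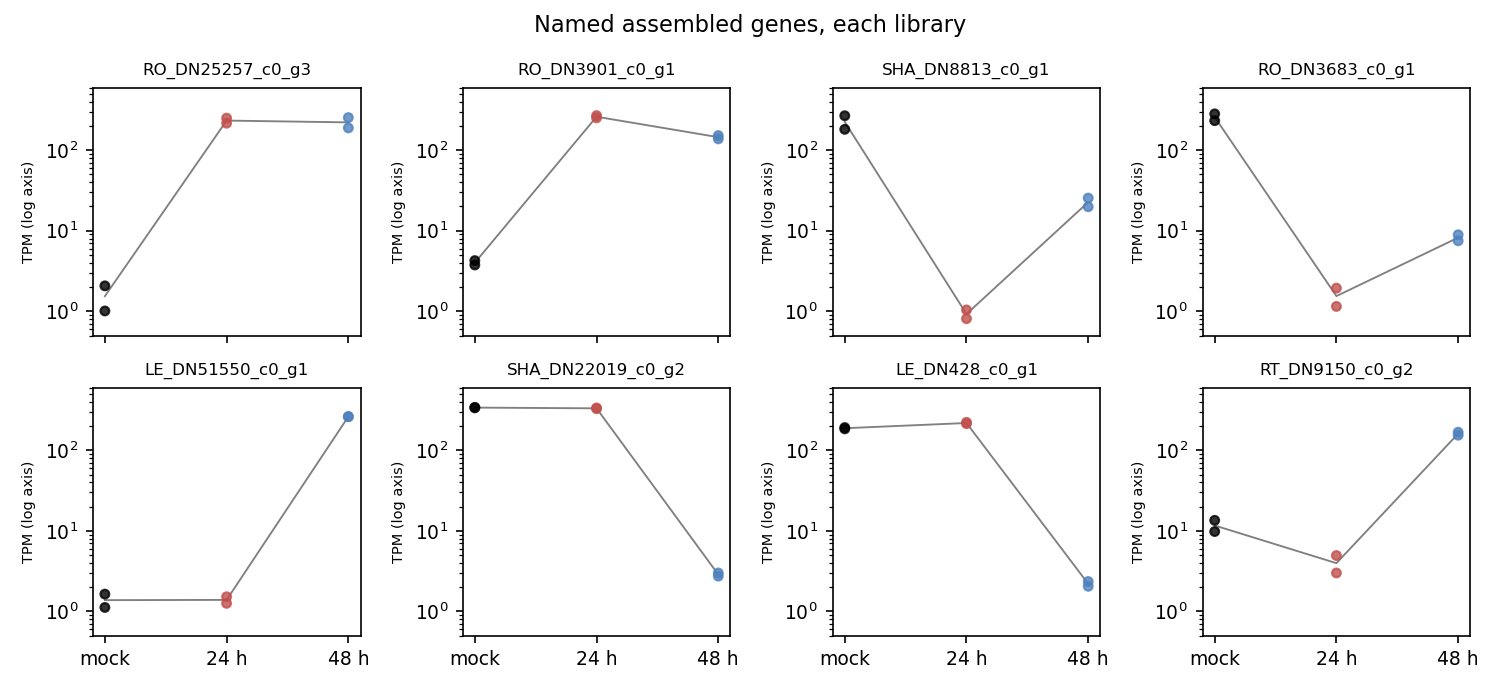
TPM (log axis) of the 8 named assembled genes in mock, 24 h and 48 h seedlings. Points are libraries, 2 per group, and grey lines join the group means. RO_TRINITY_DN25257_c0_g3 has means of 1.54 TPM in mock, 233 TPM at 24 h and 221 TPM at 48 h, while LE_TRINITY_DN51550_c0_g1 rises only at 48 h and SHA_TRINITY_DN22019_c0_g2 falls only at 48 h.

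Genes were then grouped by time course. In all, 15000 genes (46.5%) changed at either time by the moderated F test of limma. The same direction was called at 24 h and 48 h for 2840 genes, 1878 higher and 962 lower, which was 55.0% of the genes called at 24 h. Of these, 1628 did not pass the test between the times, 919 moved further from mock at 48 h, and 293 moved back toward it. This subdivision was not repeated after rescaling, although the balance of the test between the times depended on the scaling. RO_TRINITY_DN3901_c0_g1 was among the genes that moved back, at 260 TPM at 24 h and 145 TPM at 48 h. RO_TRINITY_DN25257_c0_g3 was at 233 and 221 TPM, a difference that did not pass (adjusted p = 0.77 by limma). The named genes lowest at 24 h also moved back in part: SHA_TRINITY_DN8813_c0_g1 was at 22.6 ± 4.0 TPM and RO_TRINITY_DN3683_c0_g1 at 8.21 ± 0.99 TPM at 48 h (SD, n = 2 libraries), both still below mock and above 24 h by limma. Like RO_TRINITY_DN3901_c0_g1, they were named for large changes at 24 h, a choice that favours a move back.

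A late class, called at 48 h against both mock and 24 h but not at 24 h, held 6884 genes, 1948 higher and 4936 lower. Their median log2 change against mock at 48 h was 0.88 for the higher and -0.63 for the lower genes. A transient class, called at 24 h, not called at 48 h and differing between the times, held 1322 genes, 999 higher and 323 lower at 24 h. Opposite directions at the 2 times were called for 595 genes, 341 of them higher at 24 h and lower at 48 h. After trimmed-mean rescaling the late class held 6167 genes, 3126 higher and 3041 lower. The transient class then held 999 genes, 386 higher and 613 lower, and the genes with the same direction at both times numbered 2705, 1455 higher and 1250 lower. Of the 593 genes then called in opposite directions, 132 were higher at 24 h. Without 24 h replicate 1 the same-direction class fell to 1538 genes and the transient class to 508, and without 48 h replicate 2 the late class fell to 4537. Without 24 h replicate 2 the same-direction class held 1588 genes and the transient class 538, and without mock replicate 2 they held 1837 and 829. The opposite class fell without any library: to 380 and 345 genes without mock replicates 1 and 2, to 277 and 249 without 24 h replicates 1 and 2, and to 387 and 374 without 48 h replicates 1 and 2.

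Both treatment times were compared with the same mock libraries, so their results share chance values. Of the genes higher at both times, 560 were to be found from independent lists of these lengths, against 1878 observed, and of those lower at both times 368 against 962. In 100 simulations of unchanged groups, at most 1 gene in each direction was called at both times; with no changed genes almost none are called, so this does not measure what the shared libraries add to the overlap. With a separate mock library for each time, 1159 genes were higher at both times, against 285 from independent lists, and 594 were lower, against 181, when 24 h was set against mock replicate 1. With 24 h set against mock replicate 2 the numbers were 1225 against 340 and 716 against 256. These fits had 1 mock library per comparison and took the spread from the treated groups. That spread, like the spread of the main fit, served both times, so calls can coincide more often than in independent lists. Across genes, the fold changes at 24 h and 48 h correlated with r = 0.452, while unchanged groups with shared controls gave a mean r of 0.501. Their covariance was 0.140, against 0.0169 for unchanged groups, a difference of 0.123. With separate mock libraries r was 0.351 and 0.321, and the covariance 0.115 and 0.111. The same sign was found in 59.1% of genes, against 66.7% for unchanged groups, and in 55.2% and 54.9% with separate mock libraries. In unchanged groups, r and the share of equal signs come from the shared mock libraries alone. Lower observed values therefore do not show that the 2 times agreed less than by chance.

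Genes were also grouped by the 5 prefixes of their IDs, whose meaning is not given in the sources used here. The share of changed genes differed between prefixes, over genes that are not independent replicates. Each share was set against that of all other prefixes by Fisher's exact test, and p-values were adjusted over 30 tests. Calls also depended on abundance: at 24 h, 5.4% of genes under 5 TPM were higher, and 17% of those at 100 TPM or more. Abundance was not compared between prefixes, so prefix differences cannot be told apart from differences in abundance. Genes with the prefix RT were more often higher than mock and less often lower at both times. At 48 h, 18.9% of the 6121 RT genes were higher, against 15.2% of the others (adjusted p = 2.45e-11), and 20.3% were lower, against 23.0% (adjusted p = 1.65e-05). At 24 h, 12% of RT genes were higher, against 10.7% (adjusted p = 0.00628), and 4.10% were lower, against 5.29% (adjusted p = 0.000245). Genes with the prefix LA were less often higher, with 9.24% against 11.5% at 24 h (adjusted p = 7.92e-08) and 13.1% of 7817 genes against 16.7% at 48 h (adjusted p = 6.04e-14). More of the LA genes were lower at 48 h (24.5% against 21.9%, adjusted p = 8.87e-06). Genes with the prefix LE were more often lower, with 6.34% against 4.83% at 24 h (adjusted p = 3.82e-05) and 24.6% against 22.1% at 48 h (adjusted p = 0.000245), and at 24 h they were less often higher (9.97% against 11.1%, adjusted p = 0.0237). RO genes were more often higher at 24 h (12.5% against 10.6%, adjusted p = 3.82e-05) and at 48 h (17.0% against 15.6%, adjusted p = 0.00878), and less often lower at 48 h (21.2% against 22.9%, adjusted p = 0.00729).

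Between the times, genes higher at 48 h than at 24 h were more frequent with LE (13.3% against 10.7%, adjusted p = 3.64e-07) and RT (13.2% against 10.6%, adjusted p = 7.5e-08). They were less frequent with LA (8.49% against 11.9%, adjusted p = 3.78e-16) and SHA (9.97% against 11.4%, adjusted p = 0.00246). Lower genes were more frequent with LA (30.1% against 28.0%, adjusted p = 0.000613) and less frequent with RT (26.2% against 29.0%, adjusted p = 3.8e-05). The prefix comparisons not given here did not pass. After trimmed-mean rescaling the differences for the prefixes kept their direction and passed, with 3 exceptions that did not pass: higher LE genes at 24 h (adjusted p = 0.368), higher RO genes at 48 h (adjusted p = 0.125), and lower LA genes between the times, whose shares were then 15.5% against 15.6% (adjusted p = 0.99). SHA genes were then also less often higher at 48 h than in mock (18.6% against 19.8%, adjusted p = 0.0438), and LE genes more often lower at 48 h than at 24 h (17.6% against 15.2%, adjusted p = 4.23e-05).

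Among the 100 most abundant genes, 11 were higher and 22 lower at 24 h than in mock, and 35 were higher and 24 lower at 48 h. At least 2-fold changes were found in 4 higher and 11 lower genes at 24 h, and in 12 higher and 14 lower genes at 48 h. Between the times, 36 of the 100 were higher and 22 lower at 48 h. After trimmed-mean rescaling the numbers were 8 and 24 at 24 h, 34 and 21 at 48 h, and 44 and 11 between the times.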

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

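The definition of a step at 48 h and the tests on harvest circumstances, on reads moving within and between components and on the scaling of the balance were chosen only after the result was seen. The comparison of the treatment times gave 12756 genes that differed between 24 h and 48 h, or 10849 after trimmed-mean rescaling. Without untreated libraries at these times, such differences cannot be put down to 2,4-D alone. Against mock, 595 genes were called in opposite directions at the 2 times. Of the 8 named genes, 7 differed between the times by limma at the adjusted threshold of 0.05, of which 4 had been named for their change in that same comparison and so had to pass. The 3 others were named for large changes at 24 h, and the same 24 h libraries enter the difference between the times. That choice favours a move back toward mock. For these 3 the log2 difference, 48 h minus 24 h, was -0.84 for RO_TRINITY_DN3901_c0_g1, 3.61 for SHA_TRINITY_DN8813_c0_g1 and 1.87 for RO_TRINITY_DN3683_c0_g1. For the 4 it was 5.05 for RT_TRINITY_DN9150_c0_g2 and, in genes that stood close to mock at 24 h, 6.78 for LE_TRINITY_DN51550_c0_g1, -6.43 for SHA_TRINITY_DN22019_c0_g2 and -6.10 for LE_TRINITY_DN428_c0_g1.

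The last 3 belong to a wider pattern of genes that step at 48 h alone: at least 10 TPM in 1 group, mock and 24 h within 0.5 on the log2 scale, and 48 h at least 8-fold from both. There were 57 such genes, 29 higher and 28 lower, of which 4 were also called at 24 h against mock with changes under 0.5, against 2 that stepped at 24 h alone and 17 in mock alone. Trimmed-mean scaling factors of the libraries lay between 0.911 and 1.1, so scaling of this size could not make an 8-fold step. After that rescaling 87.7% of the 57 still stepped, which factors this small nearly fixed in advance, so that share decides nothing further. Against reads moving within an assembly component, 55 of the 57 were the only gene listed of their component. In the other 2 the rest of the component took up at most 4.23% of the change in the opposite direction. A move of reads between similar genes of different components, as plants of another genotype could give, stays open without sequences: the rising genes gained 137.8% of the TPM that the falling ones lost, which decides nothing. A late effect of 2,4-D is untested too, and it cannot be told apart from harvest time, plant age or plant batch, since there are 0 untreated libraries at 48 h.

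The share of higher genes at 24 h was 68.4% in the deposited TPM and 46.0% after trimmed-mean rescaling. That rescaling centres the log ratios, so the move toward an even split was built in and decides nothing about whether the surplus of higher genes comes from the scaling of the TPM. Leaving out the 100 most abundant genes and rescaling the rest lowered the median log2 change of the other genes at 24 h from 0.098 to 0.055, a value between those set for and against a changing share of these genes as the cause, which stays open. TPM alone cannot show whether the total RNA per seedling changed.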

How the results depend on the processing

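In the comparison that named them, the named genes kept their direction and their side of the threshold in all 180 values run under the alternatives, with a highest adjusted p of 0.00165 by limma. They had been chosen for the largest changes past the threshold, which nearly fixed this in advance. It therefore says nothing about how other genes depend on the processing. Of the values run for counts, classes and correlations, 194 stayed close to the reported value (counts within 1.5 times of it) and 63 moved further. The late, transient and opposite classes, the separate mock libraries and the alternatives for the replicate correlations were chosen after seeing the data. With no filter, 3093 genes changed at 24 h (2031 higher, 1062 lower), the same direction was called at both times for 1766, the transient class held 785 and opposite directions were called for 285; 71270 genes were then tested. Trimmed-mean rescaling gave 2150 higher and 2524 lower genes at 24 h, and 5837 higher and 5012 lower at 48 h against 24 h, where quantile normalization gave 4928 higher and 5802 lower; both centre the log ratios between libraries near 0. Without the variance trend, 349 genes had opposite directions; the cause was not tested. Requiring at least 2-fold left 1119 genes at 24 h (666 higher, 453 lower), 3440 at 48 h (1681 and 1759) and 2984 between the times (1227 and 1757), a stricter criterion by construction. Leaving out 1 library at a time, which assumes that a lone library varies like the other groups, gave 2421 to 4163 genes at 24 h (1503 to 2786 higher, 896 to 1459 lower), 4792 to 6671 lower genes at 48 h, and 8224 to 12897 between the times (5672 to 9204 lower). It also gave 1538 to 2402 genes with the same direction, 4537 to 6234 late, 508 to 1097 transient and 249 to 387 opposite, and r between the fold changes from 0.417 to 0.509. Separate mock libraries for the 2 times gave 1753 genes with the same direction and r = 0.351 with 24 h against mock replicate 1, and 1941 genes and r = 0.321 with 24 h against mock replicate 2; r no longer holds the spread of shared libraries. Replicate correlations in mock, at 24 h and at 48 h were 0.965, 0.971 and 0.972 with a pseudocount of 0.1, 0.993, 0.994 and 0.995 with 5, and 0.988, 0.991 and 0.992 with a filter of 5 TPM; with no filter the mock value was 0.988. The deviations of same-numbered libraries correlated at 0.052 between mock and 24 h, -0.0085 between mock and 48 h, and 0.030 between 24 h and 48 h. These low values across genes gave little sign of pairing by replicate number, but they cannot exclude it. The replicate block gave 4814 genes at 24 h, 12137 at 48 h and 12458 between the times. No alternative for the gene lists was run, since no list could be matched to the IDs. Read depth is unknown, so what it limits cannot be stated.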

Other observations

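Genes above 0 in 1 group and listed at 0 in all 4 other libraries numbered 1584 in mock, 2568 at 24 h and 1821 at 48 h. Of these, 0 in mock, 1 at 24 h and 2 at 48 h had at least 1 TPM in both libraries of the group, and the highest group mean was 2.21 TPM, at 24 h. Genes listed at 0 in 1 group alone were not counted. The 24 h libraries listed more genes above 0 (59991 and 58977) than the mock libraries (56149 and 56506) or the 48 h libraries (56711 and 56992), which cannot be set against depth, since it is unknown. By abundance, in a split chosen after the data were seen, changed genes were most frequent at 100 TPM or more on average: of those 1672 genes, 284 were higher and 216 lower at 24 h, and 460 were higher and 524 lower at 48 h. Under 5 TPM, 687 of 12713 genes were higher and 265 lower at 24 h, and 1312 were higher and 1538 lower at 48 h. The log2(TPM + 1) scale understates changes of low genes, so these counts do not show that abundant genes responded more often. After trimmed-mean rescaling, the genes under 5 TPM split into 455 higher and 325 lower at 24 h, and into 1509 higher and 1322 lower at 48 h. The 1672 abundant genes then split into 156 higher and 327 lower at 24 h, and into 550 higher and 374 lower at 48 h. That rescaling centres the log ratios and divides all TPM of a library by the same factor. On the log2(TPM + 1) scale this shifts low genes less than abundant ones, so the contrast between them is not free of the scaling.

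The genes that fell most at 24 h also differed between the mock libraries; the test on growth state was chosen only after the result was seen. Of the 85 genes called at least 4-fold lower at 24 h, 79 (92.9%) were higher in mock replicate 2 than in mock replicate 1. The median difference over the 85 was 0.38 on the log2 scale. All 85 were at least 2-fold below mock replicate 1, which their choice at 4-fold below the mock mean nearly fixed in advance. Of the 86 genes called at least 4-fold higher, 37.2% were higher in mock replicate 2. Against a choice of genes by a high mock replicate 2, 84.7% of the 72 genes chosen by their fall against mock replicate 1 alone were higher in replicate 2, and against a difference in scaling, the mock libraries differed by a median of 0.0056 over all tested genes. A difference in growth state or handling between the mock samples is a hypothesis that cannot be told apart from other causes, because 0 label fields besides the title differ between them.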
